A study of Homo sapiens with 3 samples.

How the data were processed

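Human embryonic stem cells with a GATA3 reporter were grown on feeder layers of mouse embryonic fibroblasts, moved to matrigel, and exposed from the next day to 1 µM A83-01 and 0.1 µM PD173074. Cells were taken after 2, 3 and 4 days, with 1 droplet library of RNA 3' ends per day. The deposited table holds UMI counts per gene and cell barcode, which per the labels came from Cell Ranger 4.0.0 and the GRCh38 build. The values are whole numbers with a different total for each barcode. The gene annotation, cell calling, gene and barcode filters and handling of doublets are not given in the sources used here. The table has 23879 genes, each with a count in at least 3 barcodes, and 6076 barcodes, all of which carry the day of their library. Its lowest UMI total per barcode is 500. Reads from feeder cells, aligned to a human build, cannot be recognised in such a table.

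Cells with at least 500 genes and at most 20% mitochondrial counts were kept: 1718 of 1949 at day 2, 1876 of 1978 at day 3 and 2003 of 2149 at day 4. Median genes per cell were 6796, 6652 and 6278, and median mitochondrial shares 6.66%, 6.31% and 5.02%. UMIs were summed per library and expressed as CPM. Each level has an exact 95% Poisson interval, each ratio of 2 levels an interval from the exact binomial distribution of its counts, and each share of cells an exact Clopper-Pearson 95% binomial interval. Where no cell was found, the limit given is the share that 3 cells would make. These cover counting error only. A ratio to a library with 0 counts is a lower bound against a floor of 3 counts per library. With 1 library per day, differences between days have no replicate error, no test was made, and no gene is called changed.

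Gene ratios are log2 of CPM plus 1. For 32 gene lists (454 entries, 15 of them absent from the table), 13 of them cell type markers, the median log2 ratio was taken over members with at least 5 CPM in at least 1 of the 2 libraries compared. Its percentile was found among 10000 random lists of the same size matched on mean expression, which sets it against other genes of the same 2 libraries. Genes were counted as 2-fold higher or lower by the same log2 ratio. The lists, the filters, the comparisons, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named, among genes with at least 20 CPM in at least 1 of the libraries compared, the 15 with the largest log2 ratio in each direction for day 4 against day 2 and the 8 in each direction for the other comparisons. It also named up to 4 members of each list, by size of the ratio among those with at least 5 CPM in 1 library, and GATA3. Mitochondrial, ribosomal protein, XIST and Y-linked genes were left out. Genes outside the rule, L1TD1, SDC1, BMP4, BMP7, MSX2 and VTCN1, were named after their values were seen, and genes that the rule named for 1 comparison, such as ISL1 and COL1A1, are also given in others. Within classes of cells, the genes named were taken from the 8 with the largest ratio each way, or were list members chosen after their values were seen.

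On counts simulated from the 3 libraries pooled, at the depth of each library, 200 of 5798 eligible genes were given known ratios. All estimates (100%) lay within 0.2 log2 units of them, the intervals covered the true ratio for 96.0% to 96.5% of genes, and 0 of 20 unchanged lists were called. This tests counting error and not differences between cultures.

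All kept cells were clustered together without integration: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes (XIST and Y-linked genes left out) were scaled with a limit of 10, and 30 principal components, 15 neighbours and Leiden resolution 0.5 with seed 1 gave 11 clusters. Leading genes of a cluster had at least 50 CPM and the highest ratio to all other cells. A list named a cluster when it had the most enriched markers (at least 5 CPM and 2-fold over the other cells), at least 3 of them, and the most among the 10 leading genes, at least 1. Amnion was taken where it tied with another list, as it did with mesenchyme in cluster 4. This naming rule, the joining of clusters 4, 7 and 9 and the cell cycle thresholds were chosen after seeing the data. Levels within a class were compared where each library had at least 20 cells. For shares of cells with UMIs of a gene or list, cells were thinned at random to 21500 UMIs, which left out 266 cells at day 2, 128 at day 3 and 158 at day 4 with fewer. The narrower co-detection measure took list members under 30 CPM at day 2 and at 5 CPM or more at day 4, with 10 UMIs per list. It was set after a look at a chosen subset of genes at 5, 10 and 20 UMIs. Scrublet was run per library. It marked 11 of 5597 cells (0.197%), too few to be of use as a filter, and the 2% of cells with the highest scores were taken in its place as an alternative.

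Most alternatives changed 1 choice at a time. The stricter cell filter moved both of its limits together. For the cell cycle shares, the lower depth of 10750 UMIs per cell came with thresholds of 25 and 20 UMIs in place of 50 and 40. The alternatives were TMM factors (edgeR 4.0.16 in R 4.3.3, used for these factors alone) or median-of-ratios size factors, the mean over cells of each cell's CPM, all deposited barcodes, at least 2000 genes and at most 10% mitochondrial counts, a prior of 0.1 or 5 CPM, and a gene filter of 1 CPM or none. For cells they were Leiden resolution 0.25 or 1, 1000 or 4000 variable genes, cell cycle genes left out, thinned cells, doublets removed, and other depths and thresholds. Alternatives added after seeing the data were the top 2% of doublet scores removed, marker and named genes left out of the clustering, thinned cells within classes, no thinning for the cell cycle shares, and all settings of the narrower co-detection measure. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0. Gene positions came from GENCODE 29.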

Results

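Human embryonic stem cells that carry a reporter at GATA3, a transcription factor of trophoblast and amnion, were treated with A83-01 and PD173074 and sampled after 2, 3 and 4 days. A83-01 inhibits the receptors of Activin, NODAL and TGF-beta, and PD173074 inhibits FGF receptors. The question of the series, as its title gives it, is how trophoblast-like syncytia arise and detach from a cell layer that resembles amniotic ectoderm. The droplet libraries held 1718 cells at day 2, 1876 cells at day 3 and 2003 cells at day 4 after filtering. These carried 82412443, 98218849 and 89604482 unique molecular identifiers (UMIs), with medians of 48290, 50454.5 and 40480 UMIs per cell. Each day had 1 library, so there was no spread between replicates, no test between days was possible, and day and library cannot be told apart. Levels are in CPM, the UMIs of a gene per 1000000 UMIs of its library, with exact 95% Poisson intervals, and shares of cells have exact 95% binomial intervals. These intervals, given in brackets for the main values, cover counting error only. Genes are identified by symbol, as in the deposited table, and positions are those of GENCODE 29 on GRCh38.

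GATA3 (chromosome 10, 8045378 to 8075203, plus strand) was at 257 CPM (254 to 261) at day 2, 641 CPM (636 to 646) at day 3 and 611 CPM (606 to 616) at day 4. The level was 2.49-fold (2.45 to 2.53) higher in the day 3 library and 2.37-fold (2.34 to 2.41) higher in the day 4 library than in the day 2 library. With cells thinned to 21500 UMIs, 88.6% (86.9 to 90.2) of cells held a GATA3 UMI at day 2, 99.0% (98.4 to 99.4) at day 3 and 97.3% (96.4 to 98.0) at day 4. No cell class in these libraries lacked GATA3 UMIs, so there was no class against which to set a background from free RNA. The reporter insertion can alter the 3' end that these libraries count.

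Day 4 was compared with day 2 to ask which programmes differed most over the treatment. Genes of the hormone-producing syncytium of the placenta were far higher in the day 4 library: all 14 measured members of the syncytiotrophoblast list were at least 2-fold higher, with a median log2 ratio of 3.80. CGA (chromosome 6, 87085498 to 87095406, minus strand), the alpha subunit of chorionic gonadotropin, had 0 UMIs at day 2 and 1213 CPM at day 4, at least 33316-fold higher against a floor of 3 counts per library. CYP19A1, the aromatase that makes estrogens, was at 0.0849 and 111 CPM, 1301-fold (631 to 3237) higher. ERVFRD-1 and ERVW-1, the envelope genes for the fusion proteins syncytin-2 and syncytin-1, stood at 26.2 and 15.4 CPM at day 4. ERVFRD-1 was at least 720.2-fold higher and ERVW-1 115-fold (64.1 to 231) higher than at day 2. HSD3B1, which makes progesterone from pregnenolone, had 0 UMIs at day 2 and 25.8 CPM at day 4, at least 709-fold higher. SDC1, a heparan sulfate proteoglycan of the syncytial surface, was 12.3-fold (11.1 to 13.7) higher, at 56.8 CPM. PSG1, PSG3 and XAGE3 of this list were absent from the table, and UMIs of close paralogs such as ERVV-1 and ERVV-2 are uncertain. Members under 5 CPM in both libraries were not measured, so a gene low at day 2 could enter only by being higher at day 4. Among those left out, CGB3, CGB5, CGB7 and CGB8 stood at 2.10, 0.0335, 0.0446 and 0.123 CPM at day 4, and PSG4 at 0.279 CPM. CSH1, at 0.497 and 0.0446 CPM, was alone among those left out in being lower at day 4.

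Further placental lists, some of which share genes with the syncytiotrophoblast list, were higher too, while those of shared factors and of cytotrophoblast lay near 0. The retroviral list shares ERVW-1, ERVFRD-1, ERVV-1 and ERVV-2 with the syncytiotrophoblast list, and the steroid hormone list shares CYP11A1, CYP19A1 and HSD3B1 with it. Among placental growth factors and imprinted genes, 9 of 11 measured members were at least 2-fold higher, with a median of 3.76, or 1.89 with no gene filter. PGF, an angiogenic growth factor, was at 1.32 CPM at day 2 and 263 CPM at day 4, 199-fold (165 to 242) higher. PAPPA2, a protease that cleaves IGF-binding proteins, was at 0.0971 and 48.5 CPM, PHLDA2 at 5.89 and 144 CPM, and VEGFA at 3.54 and 71.8 CPM. Of the steroid hormone synthesis genes, 6 of 10 were at least 2-fold higher (median 1.84), among them HSD17B1, which makes estradiol, at 3.36 and 103 CPM. The endogenous retroviral list had 5 of 9 members at least 2-fold higher and 1 lower (median 2.29, or 0.51 with no gene filter). The lower member was ESRG, a transcript known from pluripotent cells, at 148 and 16.4 CPM. Of the extravillous trophoblast list, 3 of 4 measured members were at least 2-fold higher (median 2.94, or 0.74 with a gene filter of 1 CPM): HLA-G, MMP2 and ITGA5. MMP2 and ITGA5 are also in the mesenchymal transition list. HLA-G, a nonclassical HLA gene, was at 0.413 and 25.8 CPM, with reads that paralogs of the HLA family can share. The list of factors shared by trophoblast and amnion had a median of 0.23, just above the range of random lists, with 4 members at least 2-fold higher, among them GATA2 (60.4 and 181 CPM), and CDX2 and DLX5 at least 2-fold lower. CDX2, a homeobox gene of early trophoblast and hindgut, was at 23.8 and 2.97 CPM. The cytotrophoblast list had 3 of 9 members at least 2-fold higher, EGFR, VGLL1 and ITGA2, and a median of 0.20, within the range of random lists.

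Amnion and mesenchyme genes were also higher in the day 4 library, though not every member. Of the amnion list, 7 of 12 measured members were at least 2-fold higher and 2 were lower, with a median of 2.32. IGFBP5 (chromosome 2, 216672105 to 216695525, minus strand), an IGF-binding protein, was at 24.2 and 475 CPM, 19.7-fold (18.8 to 20.6) higher. GABRP (chromosome 5, 170763350 to 170814047, plus strand), a GABA receptor subunit found in epithelia, was 15.3-fold (14.5 to 16.2) higher, at 246 CPM. HEY1, a transcriptional repressor downstream of Notch, was 20.3-fold (17.1 to 24.3) higher, and ANXA1, a phospholipid-binding protein, 9.88-fold (9.58 to 10.2) higher. ISL1 (chromosome 5, 51383391 to 51394738, plus strand), a LIM homeobox transcription factor, went the other way: 27.2 CPM at day 2, 1.66 CPM at day 3 and 4.35 CPM at day 4, 6.24-fold (5.61 to 6.97) lower at day 4 than at day 2. BAMBI, a pseudoreceptor that dampens TGF-beta signals, was the other lower member, at 37.2 and 4.29 CPM.

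The mesenchyme and fibroblast list had 4 of 7 measured members at least 2-fold higher and a median of 1.94, or 0.90 with no gene filter. LUM (chromosome 12, 91102629 to 91111831, minus strand), the collagen-binding proteoglycan lumican, had 3 UMIs at day 2 and 38.4 CPM at day 4, 1054-fold (360.4 to 5114) higher. COL6A3 was at 0.631 and 15.9 CPM, and COL3A1 at 0.109 and 6.50 CPM. In contrast, COL1A1, the main collagen chain of fibroblasts, was at 37.7 and 27.7 CPM. Of the mesenchymal transition list, 6 of 10 members were at least 2-fold higher (median 1.10, or 0.64 with a prior of 5 CPM). VIM, the intermediate filament vimentin, was at 36.8 and 763 CPM, 20.7-fold (20.0 to 21.5) higher, and SNAI2, a transcriptional repressor of epithelial genes, at 0.704 and 34.4 CPM. Epithelial adhesion genes as a list were level (median -0.01, 12 of 15 within 2-fold). CLDN10, a tight junction claudin, was the 1 lower member and among the most reduced genes of all, at 1048 and 32.3 CPM, 32.4-fold (31.2 to 33.7) lower.

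Pluripotency and BMP target genes were lower in the day 4 library. Of the pluripotency list, 7 of 13 measured members were at least 2-fold lower and none were at least 2-fold higher, with a median of -1.04. POU5F1 (chromosome 6, 31164337 to 31180731, minus strand), which encodes the core pluripotency factor OCT4, was at 447 and 28.8 CPM, 15.5-fold (14.9 to 16.1) lower. SOX2, its partner, was at 46.0 and 4.90 CPM, 9.39-fold (8.50 to 10.4) lower. L1TD1, an RNA-binding protein of pluripotent cells in the same list, was at 311 and 434 CPM. MIR302CHG, the host transcript of the miR-302 microRNAs, was at 149.9 and 1.76 CPM, 85.0-fold (72.7 to 100.1) lower. Of the BMP targets, 7 of 13 were at least 2-fold lower and 3 at least 2-fold higher (median -1.12). ID1, a direct target of BMP signalling, was at 955 and 41.8 CPM, 22.9-fold (22.1 to 23.6) lower. ID4 and SMAD6 were lower too, at 13.3 and 0.837 CPM, against 153 and 18.8 CPM at day 2. The 3 higher BMP targets were HEY1, GATA2 and BMP7. The naive pluripotency list had 4 of 5 members lower (median -1.62, or -0.37 with no gene filter; ALPG, DPPA3, DNMT3L and KLF5). Of the primordial germ cell list, 2 of 6 were lower (median -0.59), DPPA3 and KLF4. Of the WNT targets, RNF43 and FZD7 were lower and TNFRSF19 higher, with a median of -0.58 over 6 genes, or -0.38 with a prior of 5 CPM.

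**Figure D1:**
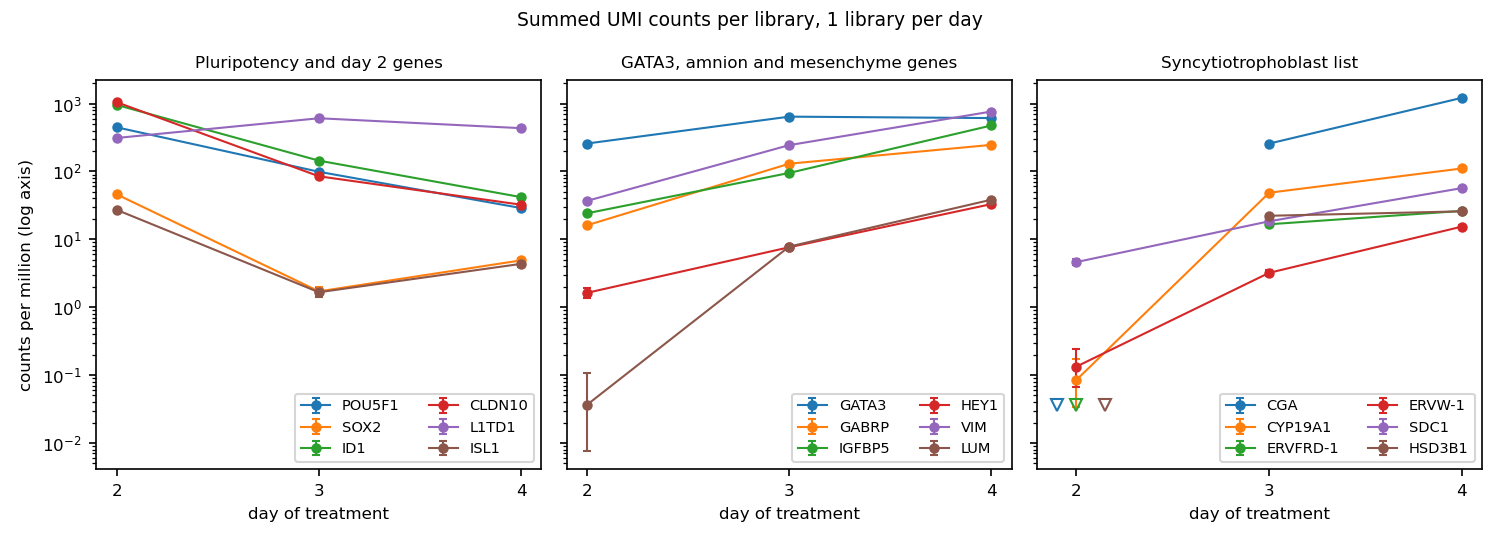
Levels of 18 genes in CPM on a log axis against day of treatment, 1 library per day; bars are 95% Poisson intervals and open triangles mark the limit of 3 counts for genes with 0 UMIs. POU5F1, SOX2, ID1 and CLDN10 were lower at day 4 than at day 2, and CGA was at 257 CPM at day 3 and 1213 CPM at day 4.

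Cell cycle lists were moderately lower at day 4. The S phase list had a median of -0.78, with 5 of 28 members at least 2-fold lower, such as MCM2, a subunit of the replicative helicase (38.6 and 14.5 CPM). The G2 and M phase list had a median of -0.39, or -0.59 as the mean over cells, with BUB1, a mitotic checkpoint kinase, the only member of 32 at least 2-fold lower. CDKN1C, an imprinted inhibitor of cyclin-dependent kinases, was at 92.0 and 1259.9 CPM, 13.7-fold (13.4 to 14.0) higher, while the cell cycle exit list lay within the random range (median 0.25; CDKN1C and GADD45A higher). Signalling lists split. Of the FGF and ERK targets, 4 of 6 were at least 2-fold higher (median 1.67, or 0.46 with no gene filter): IER3, SPRY4, DUSP5 and EGR1. DUSP6, the phosphatase that ERK induces and that dephosphorylates it, was lower, at 33.2 and 5.67 CPM. NODAL and TGF-beta targets had a median of 0.12. SERPINE1, the plasminogen activator inhibitor (0.133 and 11.2 CPM), and TGFBI were higher, and TDGF1, the NODAL co-receptor (7.45 and 1.46 CPM), was lower. YAP and TEAD targets were near 0 (median 0.11), with AMOTL1 higher and F3 and CCN2 lower.

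Stress and immune lists were higher at day 4. The integrated stress response list had a median of 0.89 (5 of 11 members at least 2-fold higher, such as DDIT3 at 8.79 and 42.4 CPM). The immediate early and dissociation list had a median of 0.96 (6 of 13, such as FOSB at 0.655 and 19.9 CPM). The antigen presentation and interferon list had a median of 0.80, with 3 of 10 members higher (IFI6, ISG15 and HLA-E) and HLA-B lower. Cholesterol synthesis (median 0.17) and glycolysis and hypoxia genes (median -0.05) lay within the random range. The glycolysis list had a positive mean, and VEGFA was its highest member. The surface ectoderm list (median -0.23, positive mean) held KRT17, a keratin of stratified epithelia whose counts a close paralog can share, at 0.328 and 32.5 CPM, and GRHL2, lower at 54.6 and 23.1 CPM. Lists for other germ layers were too thin for a median. The mesoderm list had HOXB1 alone (0.607 and 8.95 CPM), the definitive endoderm list GATA6 (57.3 and 30.2 CPM), the yolk sac endoderm list APOA2 (0.777 and 28.4 CPM), and the neural ectoderm list no measured gene.

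Other genes with the largest ratios came from outside these lists. KRT16, a keratin of stressed epithelia with close paralogs, was 937-fold (660.0 to 1379) higher, at 352 CPM. TRGC1, annotated as the constant region of a T cell receptor gamma chain and nearly identical to TRGC2, was at 0.0849 and 76.1 CPM, and IGF1, a growth factor, at 0.121 and 32.9 CPM. FYB1, an adaptor protein known from T cells, was at 74.7 CPM at day 4, NUPR1, a stress-induced nuclear protein, 57.4 CPM, TNFRSF1B, a receptor of tumour necrosis factor, 49.6 CPM, and KRT23, another keratin, 97.4 CPM. LGALS16, a placental galectin, had 0 UMIs at day 2 and 37.2 CPM at day 4, at least 1023-fold higher. PTN, the secreted growth factor pleiotrophin, was at 31.7 CPM at day 2 and 913 CPM at day 4. Among the genes with the largest folds in the other direction were RARRES2, the chemoattractant chemerin (242 and 6.05 CPM), SLC7A3, a cationic amino acid transporter (43.0-fold, 37.4 to 49.7), and HPGD, which inactivates prostaglandins (18.7-fold, 18.1 to 19.3). CYP1B1, RGS5, NEFM, SYT6, FXYD4 and CR1L were lower by 21.1-fold to 155-fold (RGS5 the least, CR1L the most), and the noncoding transcripts TUNAR, PCAT14 and AL591742.2 by 44.6-fold, 39.8-fold and 143-fold.

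In the comparison of day 4 with day 2, 13 lists had a median above the range of 95% of random lists matched on expression, and 7 had a median below it. Some lists share genes, so such counts, here and below, are not of independent results. The percentile describes these 2 libraries and is not a test between days. The syncytiotrophoblast median ranged from 2.49 with a prior of 5 CPM to 5.99 with a prior of 0.1 CPM, and the primordial germ cell list lay within the range with a prior of 5 CPM and with the mean over cells. The median log2 ratio of all genes was -0.04 for day 4 against day 2, -0.09 for day 3 against day 2 and 0.06 for day 4 against day 3. Scaling by TMM or by median-of-ratios factors moved it for day 3 against day 2 by 0.13 and 0.14, and median-of-ratios factors moved it for day 4 against day 3 by -0.12.

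**Figure D2:**
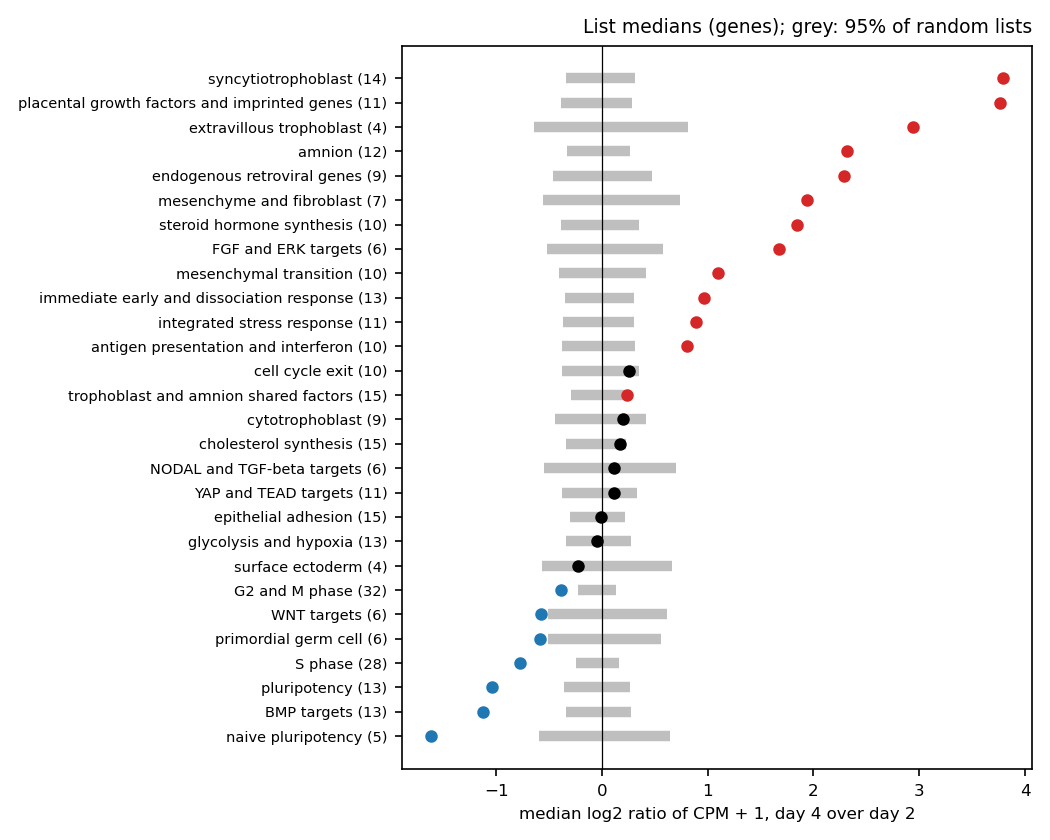
Median log2 ratio of day 4 over day 2 per gene list, with the number of measured genes in brackets; grey bars span 95% of random lists matched on expression, and red, blue and black dots lie above, below and within that range. The syncytiotrophoblast list (3.80) and the placental growth factor list (3.76) were the highest lists, and the naive pluripotency list (-1.62) was lowest.

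Day 3 was compared with day 2 to ask what differed over that interval. Much of the placental difference was present at day 3. CGA was at 257 CPM, at least 7059.6-fold higher than at day 2, and all 10 measured members of the syncytiotrophoblast list were at least 2-fold higher. The list median was 3.63, or 1.89 with no gene filter and 4.03 with genes at 0 set to their bound, a setting that left the medians of the other lists and comparisons as they were. GCM1, the transcription factor that drives trophoblast fusion, was at 0.194 CPM at day 2 and 35.7 CPM at day 3, 184-fold (113 to 322) higher. PGF was 132-fold (109 to 160.5) higher, and 9 of 11 placental growth factor and imprinted genes were at least 2-fold higher (median 3.43, or 2.01 with no gene filter), including PEG10, a retrotransposon-derived gene needed for placental development (49.3 and 201 CPM). KRT16 was at 239 CPM, FYB1 at 109.7 CPM and CLMP, an adhesion molecule of tight junctions, at 129 CPM. GJA5, the gap junction protein connexin 40, had 0 UMIs at day 2 and 34.1 CPM at day 3, at least 938-fold higher. Steroid hormone synthesis (median 1.49, 6 of 10 higher), extravillous trophoblast (1.74, 3 of 4) and endogenous retroviral genes (1.13, 3 of 6, or 1.89 with a filter of 1 CPM) were also above the random range.

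Pluripotency genes were lower by day 3: 7 of 13 measured members were at least 2-fold lower, with a median of -1.14. SOX2 was at 46.0 and 1.71 CPM, 26.9-fold (23.0 to 31.6) lower, whereas POU5F1 was at 98.9 CPM, 4.52-fold (4.42 to 4.62) lower. Of the BMP targets, 8 of 13 were lower (median -1.51), such as ID1 at 144 CPM and MSX1 at 1.19 CPM, and MSX2, GATA2 and HEY1 were higher. BST2, an interferon-induced protein that tethers virions, was at 42.8 and 0.886 CPM, 48.3-fold (39.0 to 60.4) lower. IFI16, a sensor of foreign DNA, was 18.1-fold (16.7 to 19.6) lower and ABCA1, a cholesterol exporter, 28.7-fold (24.2 to 34.3) lower. The imprinted noncoding RNA MEG3 was at 277 and 17.2 CPM. FOXH1, the partner of SMAD2 in NODAL signalling, was 19.3-fold (17.1 to 21.8) lower. The noncoding transcript PCAT14 and the complement receptor-like gene CR1L were also among the 8 most reduced genes, at 4.54 and 0.886 CPM.

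The amnion list was mixed at day 3, with a median of 1.33: 6 of 11 members were at least 2-fold higher, such as GABRP at 129.9 CPM, and ISL1, BMP4 and BAMBI were lower. The mesenchyme list lay within the random range (median 0.01), with LUM higher at 7.81 CPM and COL1A1 lower at 7.81 CPM. In all, 11 lists lay above and 7 below the random range. Those above also included FGF and ERK targets (0.51), mesenchymal transition (0.49), cholesterol synthesis (0.44, with HMGCS1 at 168 CPM), integrated stress response (0.42) and glycolysis and hypoxia (0.40, or 0.25 as the mean over cells). Those below also included naive pluripotency (-0.81), primordial germ cell (-0.80), WNT target (-0.71), S phase (-0.33) and G2 and M phase genes (-0.28), the last 2 at -0.20 and -0.14 with median-of-ratios factors. With a gene filter of 1 CPM the amnion (0.16) and extravillous trophoblast lists (0.19) lay within the random range, the second also with no filter (0.22). FGF and ERK targets did so with TMM (0.45) or median-of-ratios factors (0.47) and with the mean over cells (0.14). Lists whose mean and median differed in sign were surface ectoderm (median -0.37), YAP and TEAD targets (-0.02) and antigen presentation and interferon (0.01).

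Day 4 was compared with day 3 to ask what differed once syncytial genes were present. Mesenchyme genes differed most as a list, with a median of 1.73, or 0.94 with no gene filter, and 5 of 7 members at least 2-fold higher, among them LUM (4.91-fold, 4.54 to 5.32) and COL3A1 (0.428 and 6.50 CPM). The syncytiotrophoblast list had a median of 1.15, or 0.62 with no gene filter, with 8 of 14 members at least 2-fold higher. CGA was 4.72-fold (4.65 to 4.78) higher and ERVW-1 was at 3.21 and 15.4 CPM, while GCM1 was at 35.7 and 28.6 CPM. The amnion list had a median of 0.80, with 4 of 11 members at least 2-fold higher: TFAP2B, a transcription factor (9.21-fold, 8.04 to 10.6), IGFBP5 (5.01-fold, 4.89 to 5.12), HEY1 and ANXA1. IGF1 and TRGC1 had the largest ratios, 24.5-fold (20.6 to 29.4) and 14.9-fold (13.6 to 16.3). HOTAIRM1, a noncoding RNA of the HOXA locus, was at 4.79 and 45.7 CPM, its neighbour HOXA1 was 8.93-fold (7.83 to 10.2) higher, and ACTC1, cardiac actin, was at 43.9 and 284 CPM. LGALS16 (15.8-fold, 13.9 to 18.2) and TNFRSF1B (9.90-fold, 9.02 to 10.9) completed the 8 genes with the largest ratios upward.

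Among the genes lower at day 4 than at day 3, FABP5, a carrier of fatty acids, was at 2629 and 416 CPM, 6.32-fold (6.25 to 6.38) lower. RARRES2 was 9.96-fold (9.12 to 10.9) lower, HPGD 6.08-fold (5.87 to 6.30) lower, and PEG10, which had been higher at day 3 than at day 2, 3.54-fold (3.43 to 3.65) lower. MYC, a growth-promoting transcription factor, was at 43.0 and 11.3 CPM. EGLN3, an oxygen-sensing prolyl hydroxylase, was at 45.2 and 10.6 CPM, DIO3, which inactivates thyroid hormone, at 80.9 and 14.6 CPM, and APELA, a ligand of the apelin receptor, at 46.0 and 8.95 CPM. In all, 13 lists lay above the random range and 6 below it. With the mean over cells of each cell's CPM in place of the sum, 8 lay above, and the pluripotency (-0.18), extravillous trophoblast (0.50), primordial germ cell (0.28), steroid hormone (0.25), placental growth factor (0.09) and endogenous retroviral lists (0.31) lay within the range. So did the steroid hormone list in 3 other settings, the pluripotency and extravillous trophoblast lists with a gene filter of 1 CPM or none (-0.01 and 0.23 with none), and the glycolysis (-0.11) and endogenous retroviral lists (0.11) with no filter. Others above were antigen presentation and interferon (0.77, with ISG15 at 20.0 and 121 CPM), mesenchymal transition (0.73, or 0.46 with no filter), immediate early (0.63), extravillous trophoblast (0.59), placental growth factor (0.58), primordial germ cell (0.57), integrated stress response (0.57), endogenous retroviral (0.56), cell cycle exit (0.36, or 0.23 with median-of-ratios factors) and steroid hormone synthesis genes (0.26). Those below were naive pluripotency (-0.67, or -0.17 with no filter), S phase (-0.49), cholesterol synthesis (-0.35), pluripotency (-0.35), glycolysis and hypoxia (-0.27) and G2 and M phase genes (-0.15, or -0.27 with median-of-ratios factors). The mean and median differed in sign for the shared factors (median 0.00), cytotrophoblast (0.18), BMP target (-0.18) and YAP and TEAD target lists (-0.01).

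The 5597 cells of the 3 libraries were clustered together, without integration, to ask which cells held these genes. Of 11 clusters, 5 were named or grouped from the fixed markers. Cluster 6 was syncytiotrophoblast-like: 17 of the list's 27 members were enriched in it, and CGA, HOPX, TNFRSF1B, PGF and ERVFRD-1 led its genes. Cluster 3 was pluripotent-like, with 10 pluripotency genes enriched, led by EDN1, CYP1B1 and NEFM with SOX2 and ESRG among its 10 leading genes. The amnion markers ISL1, BMP4 and BAMBI were enriched in it too, and POU5F1, SOX2 and ESRG were also enriched in cluster 1. Clusters 4, 7 and 9 are called the GABRP-high group, a label and not a cell type. GABRP was at 489, 370.4 and 213 CPM in them, the highest levels of the 11 clusters, but in cluster 9 it was less than 2-fold above the other cells. Amnion markers were enriched in each (6, 5 and 3 genes), but in cluster 4 mesenchyme markers were as many (6, with LUM and VIM the leading genes) and cluster 7 had 4. Cluster 9 was led by CA3, CXCL14, HOTAIRM1 and HOXA1. The amnion markers enriched in cluster 9 were VTCN1, IGFBP5 and TFAP2B. The other clusters had no leading list. Cluster 1 was led by CLDN10, SLC7A3 and RGS5, cluster 2 by SLC7A4 and SMTN, cluster 5 by KRT16, and cluster 8 by S100A6. Cluster 11 was led by TRGC1 and IGF1, and cluster 10 had a median of only 1351 UMIs per cell.

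**Figure D3:**
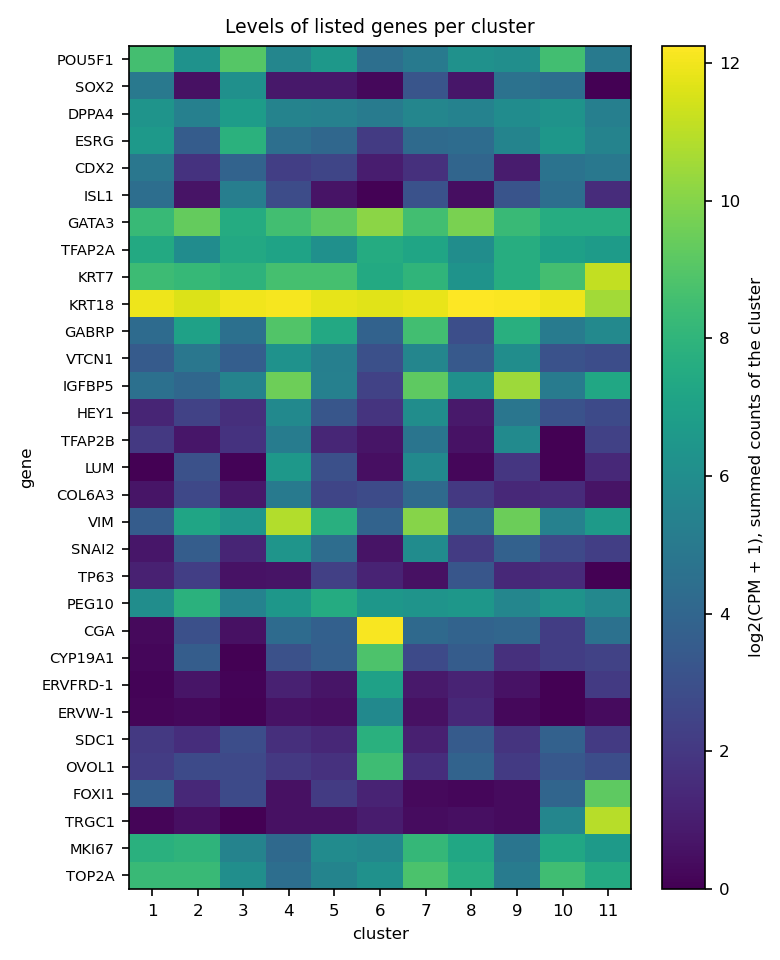
Heat map of log2(CPM + 1) of the summed counts of 31 genes in the 11 clusters, cells of all 3 libraries together. CGA, CYP19A1 and ERVFRD-1 are highest in cluster 6, LUM and VIM in cluster 4, POU5F1 and SOX2 in clusters 1 and 3, and FOXI1 and TRGC1 in cluster 11.

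No syncytiotrophoblast-like cell was found among the 1718 cells of day 2, which allows a share of up to 0.175% (3 cells of the total). The share was 12.7% (11.3 to 14.3) at day 3 and 12.2% (10.8 to 13.7) at day 4. It counts kept barcodes of the droplet libraries, so any syncytia lost before or at droplet capture would be missing from it. The GABRP-high group made up 0.116% (0.0141 to 0.420) of cells at day 2, 13.3% (11.8 to 14.9) at day 3 and 59.5% (57.3 to 61.7) at day 4. The day 2 share was 2 cells with a median of 4592 UMIs and no GABRP UMI, so it shows no GABRP-high cell at that day. At day 3 most of it was cluster 4 (159 of 249 cells), and at day 4 clusters 4 (542 cells), 7 (393 cells) and 9 (257 cells). Pluripotent-like cells made up 37.7% (35.4 to 40.1) of cells at day 2, 3.78% (2.97 to 4.75) at day 3 and 0.150% (0.0309 to 0.437) at day 4. In other clusterings this share ranged from 6.34% to 38.1% at day 2 and from 0% to 5.49% at day 3. The share counts cluster 3 and not all cells with pluripotency genes. In thinned cells of day 2, 99.5% (99.0 to 99.8) held a POU5F1 UMI. Cluster 1, with CLDN10 as its first leading gene, held 50.5% (48.1 to 52.9), 3.25% (2.50 to 4.16) and 0.0999% (0.0121 to 0.360). Cluster 2 held 30.5% (28.4 to 32.6) and cluster 5 22.7% (20.8 to 24.6) of the day 3 cells. Because the genes that define these clusters differ between the libraries, shares and gene levels restate each other in part, and a cluster held mostly by 1 library can reflect that library. Where marker and named genes were left out of the clustering, a choice made after seeing the data, the syncytiotrophoblast-like share was 0.582% at day 2, 17.9% at day 3 and 14.8% at day 4. The order of days for the GABRP-high group was the same in every clustering that gave the group, but its share ranged from 4.73% to 30.8% at day 3 and from 32.1% to 76.3% at day 4.

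**Figure D4:**
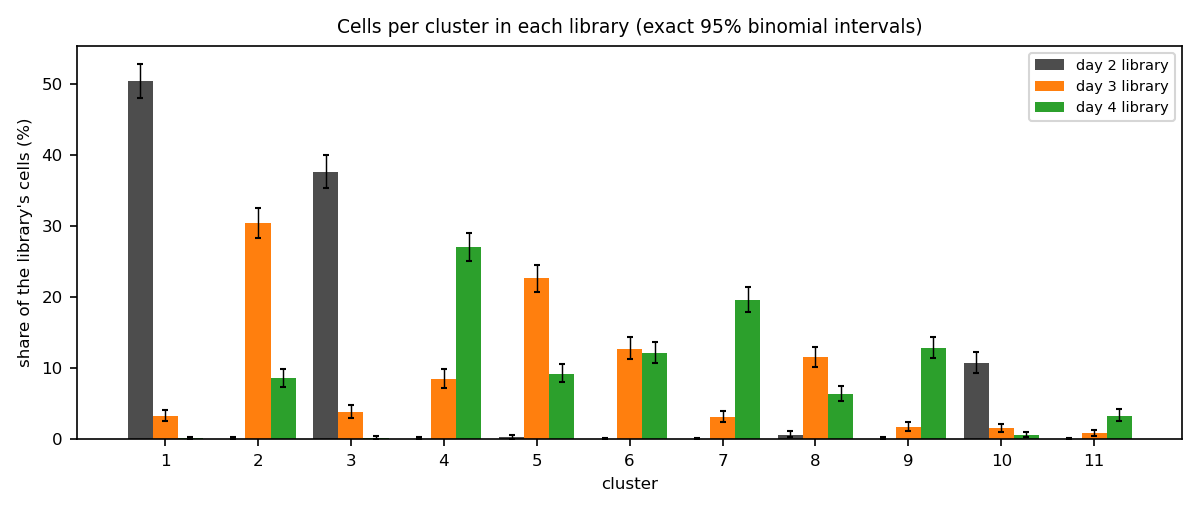
Share of each library's cells, in percent, in clusters 1 to 11 at day 2, 3 and 4; error bars are exact 95% binomial intervals. Clusters 1 and 3 held most cells at day 2, clusters 2 and 5 were largest at day 3, and clusters 4, 7 and 9 held 59.5% of cells at day 4.

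Although their share of the kept cells was similar at day 3 and day 4, syncytiotrophoblast-like cells differed in gene levels between these libraries. Among thinned cells of this class, 38.4% (32.0 to 45.1) held a CGA UMI at day 3 and 76.7% (70.6 to 82.0) at day 4. For CYP19A1 these shares were 51.8% and 65.2%, and for ERVFRD-1 21.9% and 35.2%. Outside the class, 7.02% of thinned cells held a CGA UMI at day 3 and 29.4% at day 4, which free RNA can raise. A similar size of the class thus did not mean a similar share of cells with CGA. HSD17B1, which converts estrone to estradiol, was at 138 CPM in the 239 cells of day 3 and 511 CPM in the 244 cells of day 4, 3.71-fold (3.53 to 3.90) higher. ERVW-1 was 4.24-fold (3.73 to 4.84) higher and SDC1 2.81-fold (2.66 to 2.98) higher, whereas GCM1 was level, at 146 and 142 CPM. TXNIP, an inhibitor of thioredoxin, was at 8.79 and 87.5 CPM, and PRR9, OTUB2 and RHOV were among the 8 genes with the largest ratios. POU5F1 was at 41.3 CPM at day 3 and 3.35 CPM at day 4, 12.3-fold lower, and DPRX, DIO3 and FABP5 were also lower. POU5F1 in the whole library was at 98.9 and 28.8 CPM, and free RNA from other cells adds to levels within a class by an unknown amount. The syncytiotrophoblast list had a median of 1.48 over 17 genes, 10 of them at least 2-fold higher, and the steroid hormone synthesis list a median of 0.76 over 10 genes. The immediate early and dissociation (0.80 over 13 genes), integrated stress response (0.69 over 11 genes) and antigen presentation and interferon lists (0.62 over 10 genes) were higher in the same cells, so a difference in handling of the libraries stays open. Members of the syncytiotrophoblast list define this cluster, so its median describes cells grouped by these genes. Where marker and named genes were left out of the clustering, the median was 1.61.

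In the GABRP-high group, day 4 (1192 cells, clusters 4, 7 and 9) was compared with day 3 (249 cells, mostly cluster 4). The amnion list had a median of 0.17 over 12 genes, and the mesenchyme list 0.36 over 7 genes. COL6A3, a chain of collagen VI, was at 4.49 and 24.5 CPM and TXNIP at 8.70 and 50.9 CPM. Lower at day 4 were ACTA1, skeletal muscle actin (25.9 and 0.960 CPM), NPPB, a natriuretic peptide (124 and 15.6 CPM), and MYC (33.0 and 8.27 CPM). The amnion median was 0.30 with Scrublet calls removed and 0.31 at Leiden resolution 0.25. Within cluster 4 alone, COL6A3 was at 5.80 and 38.9 CPM and COL1A1 at 20.6 and 64.9 CPM.

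Cells with many UMIs of cell cycle genes made up a smaller share at later days. With cells thinned to 21500 UMIs, the share with at least 50 UMIs of the G2 and M phase list was 56.4% (53.8 to 59.0) at day 2, 47.8% (45.5 to 50.2) at day 3 and 38.3% (36.0 to 40.5) at day 4. The share with at least 40 UMIs of the S phase list was 59.8% (57.3 to 62.4), 49.0% (46.7 to 51.4) and 24.7% (22.8 to 26.8). In syncytiotrophoblast-like cells the G2 and M phase share was 16.1% (11.5 to 21.5) at day 3 and 19.8% (14.8 to 25.6) at day 4. In the GABRP-high group it was 25.8% (20.2 to 32.0) and 37.3% (34.5 to 40.3). Without thinning, where cells differ in depth, the order of these classes turned: 43.9% (37.5 to 50.5) against 32.9% (27.1 to 39.1) at day 3 and 45.9% (39.5 to 52.4) against 43.0% (40.2 to 45.9) at day 4. In thinned cells of day 3 the median was 16 UMIs of the list in syncytiotrophoblast-like cells and 14 in the GABRP-high group. In the remaining thinned cells the G2 and M phase share was 56.4% (53.8 to 59.0) at day 2, 57.1% (54.4 to 59.8) at day 3 and 48.1% (43.8 to 52.5) at day 4. The S phase share of thinned cells at days 3 and 4 was 9.38% and 11.9% in syncytiotrophoblast-like cells and 26.2% and 24.5% in the GABRP-high group. In the remaining thinned cells it was 59.8%, 59.8% and 30.7% at days 2, 3 and 4. The counts had no gap at either threshold, so the shares grade cells and do not separate cycling from resting ones, and free RNA adds to them by an unknown amount. Without thinning, both shares over all cells were higher at day 3 than at day 2, 64.9% against 63.2% and 75.2% against 70.7%.

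Co-detection was measured to ask whether amnion and syncytiotrophoblast genes lay in the same cells. With at least 2 UMIs of each full list, 33.3% (31.1 to 35.6), 66.3% (64.1 to 68.4) and 60.7% (58.5 to 62.8) of cells held both at days 2, 3 and 4, against 29.9%, 65.3% and 60.3% expected from independent detection. This measure was near saturation, since 88.2%, 96.0% and 98.5% of cells held the amnion list. Its side of the expected share turned in thinned cells, with 12.6%, 42.2% and 44.5% against 13.3%, 43.9% and 45.0% expected. A narrower measure, set after seeing the data, used genes under 30 CPM at day 2: GABRP, VTCN1, IGFBP5, HEY1 and TFAP2B for amnion and 14 syncytiotrophoblast genes such as CGA. Its 30 CPM limit admitted IGFBP5. The amnion list members enriched in the syncytiotrophoblast-like cluster 6, GADD45G and ANXA1, are not in it. With at least 10 UMIs of each among 21500, no cell of 1452 at day 2 held both, which allows up to 0.207% (3 cells of the total). Only 0.0716 cells were expected at day 2 from independent detection, as the genes were chosen to be low then. The 0 therefore does not bear on the question. At day 3, 6 of 1748 cells held both, 0.343% (0.126 to 0.746), against 39.5 cells expected. At day 4, 29 of 1845 cells held both, 1.57% (1.06 to 2.25), against 138 expected. At days 3 and 4 the share was 3.49% and 7.32% with 5 UMIs, 0% and 0.0542% with 20 UMIs, and 4.10% and 7.04% with 10 UMIs and no thinning, each fewer than expected from independent detection. Free RNA adds to these shares by an unknown amount. Of these 35 cells, 2 were among the 2% with the highest doublet scores of their library.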

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

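All tests in this part were chosen after the results were seen. Syncytiotrophoblast list genes had a median log2 ratio of 1.48 for day 4 against day 3 within syncytiotrophoblast-like cells and of -0.23 within the GABRP-high group. The first rests on 17 genes, the other on 5 genes, with a positive mean (0.17) and inside the range of random lists (-0.25 to 0.36), so it gives no clear direction for that group. The G2 and M phase list had a median of -0.22 in syncytiotrophoblast-like cells and of 0.30 in the GABRP-high group, where clusters 4, 7 and 9 by themselves had 0.21, -0.08 and -0.12. These lists were singled out because the 2 classes of cells differed in sign by at least 0.2 each way, a limit set after the values were seen, and the difference itself was not tested. The barcodes left out by the filters held CGA at 96.1 CPM (72.8 to 125) at day 3, in 102 barcodes, and at 1259.8 CPM (1179 to 1345) at day 4, in 146 barcodes. The 231 left-out barcodes of day 2 held no CGA UMI. CGA was thus found in material outside the comparisons, at a level at day 4 near that of the kept cells. Free RNA may account for some or all of it, which was not tested.

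Mesenchyme list genes such as LUM, COL6A3 and COL3A1 were higher in the day 4 library than in the day 3 library. Against mesenchymal or feeder cells mixed into the culture, cells with at least 2 LUM UMIs held nearly as many UMIs of the epithelial keratins KRT8 and KRT18 as other cells: the lowest median, at day 4, was 93% of that of other cells, and 0 of the 234 LUM cells at day 4 and 0 of the 62 at day 3 had fewer than 10. Free RNA of LUM would reach all clusters alike, but at day 4 these cells were 135 of 491 in cluster 4, 77 of 381 in cluster 7, 0 of 227 in cluster 6 and 0 of 120 in cluster 8. LUM is a leading gene of clusters 4 and 7, so their shares are in part built in by the clustering. For doublets of mesenchymal and epithelial cells, the highest median UMI total of LUM cells, at day 4, was 91.6% of that of other cells. This cannot exclude doublets, because the other cells include clusters of deeper cells. Over all days, cluster 4 had a median of 34542 UMIs per cell and cluster 6 one of 59440. COL1A1, COL1A2 and DCN stood at 92.2, 17.2 and 6.47 CPM in the LUM cells of day 4, and POSTN at 0. Doublets and feeder cells stay open, as do, untested, a difference between the libraries other than day and an epithelial cell state that may hold these genes.

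Cluster 11, led by TRGC1, IGF1 and TMEM213 with FOXI1, TAC1 and HMX2 among its leading genes, held 0, 15 and 66 cells at days 2, 3 and 4. Against doublets of other cell types, a mixture lies between its parents, but 11 of 2023 genes chosen without regard to cluster 11 lay below 50% of their lowest level in 7 other clusters of day 4, against 0 in each of 210 sets of doublets made from cells of these clusters. The 0 was nearly fixed in advance, since the sets were made from the clusters that gave the lowest levels. A bound of 20 genes, set first, was replaced after the count was seen because a mixture allows none. On the other side, 6 of the 81 cells (7.41%) were among the top 2% of doublet scores. That was the highest share of the 11 clusters, with cluster 5 next at 3.42%. Scrublet called 2 cells of cluster 11, of 11 calls in all, so some of its cells may be doublets. Against cells from outside the stem cell culture, 8 genes of the pluripotency list had a median level in day 4 cluster 11 cells of 61.5% of that in the other day 4 cells (31.4% to 94.6%), though free RNA adds to these levels. What stays open is which cell type this is, since no fixed list names it, doublets with a type too rare to form a cluster, and whether the cluster would be found in another culture.

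Genes of the integrated stress response, of the immediate early response and of antigen presentation and interferon were higher in the day 4 library than in the day 3 library. Against a different mix of clusters in the libraries, the median over 7 clusters of the ratio within each cluster was at least 67.7% of the ratio in the whole library: 0.38 against 0.57 for stress, 0.43 against 0.63 for immediate early and 0.71 against 0.77 for interferon genes. Handling of the whole day 4 library, such as its dissociation, cannot be told apart from the day of treatment. It would raise the lists in every cluster. All 3 lists had a median above 0 in 7 of 7 clusters, the lowest being 0.0008 for immediate early genes. They were above the range of random lists in 5, 5 and 6 of 7 clusters, so these values do not decide. With 1 library per day, treatment time stays open as well.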

How the results depend on the processing

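No paired analysis was possible because each day had 1 library, and leaving out a library or splitting the samples was not possible for the same reason. Alternatives for doublet scores, for marker genes left out of clustering, for thinned cells within classes, for unthinned cell cycle shares and for the narrower co-detection were chosen after seeing the data. Of 756 list medians under 9 settings, none reversed in sign among those called, 513 moved by less than 0.1 (log2), a limit set after seeing the data, and 243 moved by more. The largest move was 2.20 for day 4 against day 2, in the extravillous trophoblast list with a gene filter of 1 CPM or none, and 1.74 for day 3 against day 2, in the syncytiotrophoblast list with no filter. The syncytiotrophoblast median for day 4 against day 2 lay between 2.49 with a prior of 5 CPM and 5.99 with a prior of 0.1 CPM, so the size of a median over genes near 0 depends on these choices. Of the lists outside the random range, 19 to 20 of 20 stayed outside it for day 4 against day 2, 16 to 18 of 18 for day 3 against day 2, and 13 to 19 of 19 for day 4 against day 3. The lowest of these, 13, came with the mean over cells of each cell's CPM, where 8 lists in place of 13 lay above the range for day 4 against day 3. It was 15 with no gene filter, where genes of few counts enter. The 30 genes named for day 4 against day 2 kept their direction and a 2-fold difference in all 9 settings. The gene filters leave these ratios as they are, and a prior cannot turn a direction. These genes have the largest ratios, so this says little about how other genes depend on the settings. The cause of the moves below was not tested, except that fewer UMIs per cell or a higher threshold lowers a share of cells by construction. Depth limits the genes with few UMIs, such as ERVW-1 and LUM at day 2, and the classes of few cells.

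GATA3 levels at days 2, 3 and 4 were 249, 675 and 601 CPM with TMM factors, 248, 682 and 596 CPM with median-of-ratios factors, and 243, 615 and 548 CPM as the mean over cells. With at least 2000 genes and at most 10% mitochondrial counts, GATA3 was at 264 CPM at day 2 and 588 CPM at day 4. In these settings, too, it was lowest at day 2 and highest at day 3. The share of cells with a GATA3 UMI was 77.4%, 95.5% and 92.0% at 10750 UMIs per cell, and 98.2% at day 3 with no thinning.

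Of 93 class shares under the alternatives, 53 stayed within their 95% interval and 40 moved. The GABRP-high group had its lowest share at day 2 and its highest at day 4 in all 10 alternative clusterings that gave it, and the pluripotent-like cells their highest at day 2. Their size depended on the setting, as these values show. With all deposited barcodes, the GABRP-high share was 20.7% at day 3 and 48.6% at day 4, and the pluripotent-like share 32.4% at day 2 and 1.11% at day 3. With at least 2000 genes and at most 10% mitochondrial counts, the GABRP-high share was 0% at day 2 and 39.5% at day 4, the pluripotent-like share 34.1% at day 2 and 0.416% at day 3, and the syncytiotrophoblast-like share 9.68% at day 4. With Scrublet calls removed, the GABRP-high share was 22.2% at day 3 and 68.0% at day 4. With the top 2% of Scrublet scores removed, it was 4.73% and 32.1%, and the pluripotent-like share 6.47%, 0% and 0% at days 2, 3 and 4. At Leiden resolution 0.25 the GABRP-high share was 24.7% at day 3 and 70.4% at day 4. At Leiden resolution 1 the pluripotent-like share was 6.34%, 0.0533% and 0% at days 2, 3 and 4. With 1000 variable genes the GABRP-high share was 9.12% at day 3 and 42.7% at day 4, and the pluripotent-like share 33.3% at day 2 and 0.267% at day 3. With 4000 variable genes the GABRP-high share was 30.8% at day 3 and 76.3% at day 4, the pluripotent-like share 35.1% at day 2 and 2.72% at day 3, and the syncytiotrophoblast-like share 14.5% at day 4. With cell cycle genes left out, the GABRP-high share was 6.50% at day 3 and 38.3% at day 4, and the pluripotent-like share 30.7% at day 2 and 0.373% at day 3. With cells thinned, the pluripotent-like share was 33.2% at day 2 and 0.229% at day 3. With marker lists and named genes left out of clustering, the syncytiotrophoblast-like share was 0.582%, 17.9% and 14.8% at days 2, 3 and 4, and the pluripotent-like share 5.49% at day 3. Clustering of thinned cells gave no cluster that met the rule for the GABRP-high group, and Leiden resolution 0.25 none for the pluripotent-like class, so these have no value.

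Within classes, the syncytiotrophoblast list median for day 4 against day 3 was 1.30 with cells thinned and 1.61 with marker lists and named genes left out of clustering. The amnion list median in the GABRP-high group was 0.30 with Scrublet calls removed and 0.31 at Leiden resolution 0.25, and the other 8 of 12 values stayed within 0.1.

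For the cell cycle, 13 of 52 shares stayed within their interval and 39 moved. The 13 were those at 10750 UMIs per cell, where the thresholds were lowered along with the depth, to 25 and 20 UMIs. All shares moved where the threshold alone was changed or thinning was left out. The G2 and M phase share at days 2, 3 and 4 was 72.9%, 66.8% and 49.2% at 0.5 times the threshold (25 UMIs), 29.8%, 24.6% and 22.5% at 2 times the threshold, and 63.2%, 64.9% and 47.1% with no thinning. The S phase share was 85.8%, 78.5% and 58.8%, then 6.75%, 2.69% and 1.73%, and 70.7%, 75.2% and 55.4% under the same settings. Over all cells, the order of days 2 and 3 was turned only with no thinning. In syncytiotrophoblast-like cells the G2 and M phase share at days 3 and 4 was 34.4% and 37.0% at 0.5 times the threshold, 6.25% and 5.73% at 2 times the threshold, and 43.9% and 45.9% with no thinning. In the GABRP-high group it was 35.6% and 46.3%, 17.3% and 23.6%, and 32.9% and 43.0% in the same order. In the remaining cells it was 72.9%, 77.8% and 60.2% at days 2, 3 and 4, then 29.8%, 29% and 27.5%, and 63.2%, 74.3% and 56.1%. The order of the first 2 classes was turned with no thinning alone, where their depths differ.

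For co-detection, 9 of 21 shares stayed within their interval and 12 moved. With all list genes, the share at days 2, 3 and 4 was 17.9%, 53.5% and 46.9% at 3 UMIs per list, and 12.6%, 42.2% and 44.5% in thinned cells. With the day-2-low genes, the share at days 3 and 4 was 3.49% and 7.32% at 5 UMIs, 0% and 0.0542% at 20 UMIs, and 4.10% and 7.04% with no thinning.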

Other observations

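The clusters, genes and lists of this part were chosen after their values were seen, and no test was made on them. Leading genes set a cluster against cells of all days and so reflect the mix of days. Levels here are therefore those of the day with most cells of the cluster, beside the other cells of that day. Cluster 8, with 11, 216 and 128 cells at days 2, 3 and 4, was led by S100A6, a calcium-binding protein, at 3380.4 CPM against 491 CPM at day 3. IL32, a cytokine, PTGES, a prostaglandin synthase, and F3, the initiator of blood clotting, were at 48.5, 79.7 and 107 CPM, against 13.5, 17.2 and 21.1 CPM. Cluster 5, of which 425 of 614 cells came from day 3, had KRT16 at 353 CPM against 211 CPM. Cluster 2, with 572 of 745 cells from day 3, had PEG10 at 269 CPM against 164 CPM and CCKBR, a gastrin receptor, at 729 CPM against 561 CPM. Of its 10 leading genes, the histone gene HIST1H1B had the largest ratio within day 3, at 75.6 CPM against 20.0 CPM. SLC7A4, FEZ1, FYB1 and SELENOM were leading genes of both cluster 2 and cluster 5. In cluster 1, by contrast, the leading gene ID1 was at 901 CPM at day 2, below the 1051 CPM of the other day 2 cells. Cluster 9, with 257 of 290 cells from day 4, had CXCL14, a chemokine, at 989 CPM against 118 CPM at day 4, CA3, a carbonic anhydrase, at 109.5 CPM against 12.4 CPM, and HOXA1 at 85.3 CPM against 15.8 CPM.

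FOXI1 (chromosome 5, 170105897 to 170109725, plus strand), a forkhead transcription factor of ion-transporting epithelial cells, was highest in cluster 11. It was at 714 CPM in the 15 cells of day 3 and 575 CPM in the 66 cells of day 4, against 3.08 and 0.739 CPM in the other cells of those days. TAC1, the precursor of substance P, was at 1091 and 1054 CPM in these cells, and TIMP3, an inhibitor of metalloproteinases, at 2032 and 3353 CPM. IGF1 was at 178 CPM at day 3 and 960.5 CPM at day 4. At day 3, 9 of the 10 leading genes were at least 10-fold higher in the cluster than in other cells. DCT, a melanin synthesis enzyme, was the exception, with 0 UMIs at day 3 and 131 CPM at day 4. Reads of TRGC1 can be shared with TRGC2.

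For day 4 against day 3, further lists had these values within classes. In syncytiotrophoblast-like cells the integrated stress response list had a median log2 ratio of 0.69 (4 of 11 genes at least 2-fold higher), the immediate early and dissociation list 0.80 (6 of 13), and the YAP and TEAD target list -0.43 (1 gene of 10 higher and 2 lower). In the GABRP-high group the same lists had medians of 0.59, 0.34 and -0.59, and cholesterol synthesis genes a median of -0.38 with none of 15 at least 2-fold lower. FGF and ERK targets lay at -0.56 there and at 0.09 in syncytiotrophoblast-like cells. The difference between the classes was not tested.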
